A study of Mus musculus with 12 samples.

How the data were processed

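Total RNA of bone marrow-derived macrophages from 2 mouse genotypes was sequenced without TNF or after 10 ng/ml TNF for 6 h, with 3 libraries in each of 4 groups. RNA was isolated with the High Pure kit (Roche) and libraries were made from 150 ng of RNA with the TruSeq Stranded Total RNA kit and Ribo-Zero Gold, which removes ribosomal RNA, per the labels' protocols. Cufflinks and the genome builds GRCm39 and mm10 are named, with no version and no role, per the submitters' processing notes. The aligner, the counting tool, the annotation, the use of strand and any filter are not given in the sources used here. Mouse strain, sex, sequencing batch and the source of each replicate are not given either.

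The authors deposited 2 tables of normalized signal per gene and library, 1 for the untreated and 1 for the TNF-treated libraries, with Ensembl gene identifiers per the file headers. The unit is stated nowhere and was read from the values. Within a library every deposited signal value was a whole multiple of 1 step (largest deviation 5.3e-05 reads, tolerance 0.001), so each value is a read count divided by 1 size factor. The steps equalled median-of-ratios size factors recomputed within each table, so the tables were normalized separately. Values are called normalized counts in the text. This unit differed from the FPKM that the plan had assumed from the name Cufflinks, and the plan's limma analysis of per-library values was applied to it with CPM in place of FPKM. Whole reads were recovered by the same steps, and the libraries held 16.9 to 23.4 M of them. Untreated Klf6-deleted libraries had reads on 19880 to 20169 genes and untreated Lyz2cre libraries on 18332 to 18846, with TNF 18231 to 18341 and 17143 to 17573. Mitochondrial genes took 1.21 to 1.74% of reads. Gene symbols came from a table that paired 22867 of the 22896 untreated and 21411 of the 21437 TNF identifiers with a symbol, and positions from GENCODE vM21 (GRCm38, the same assembly as mm10). Reads carried no molecular identifiers, so counting intervals cover counting error only. The counting could split reads between near-identical copies, so genes such as Lyz2, Pirb, Pira2 and the class I H2 genes are uncertain.

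Genotypes were compared within each table by limma with a mean-variance trend on log2(value + 1), over genes with at least 1 CPM in at least 3 libraries. P-values were adjusted by the Benjamini-Hochberg method and a gene was called changed at an adjusted p below 0.05. The difference between the genotype effects with and without TNF was tested by limma over the 4 groups, as a contrast of the within-table differences. Overlaps of calls were tested with Fisher's exact test, two-sided. Replicate numbers recur between groups, and after removal of group means the libraries of the 2 genotypes with the same number had correlations of 0.152, -0.0378 and 0.158 untreated and -0.0209, -0.0123 and -0.0295 with TNF. For 2 of the 3 untreated numbers this was above the highest for unlike numbers (0.0897 and 0.114), but the correlations were weak and absent with TNF, so samples were not paired and the pairing was tried as an alternative. The response to TNF was computed as the ratio of group levels across the tables with no test.

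Gene lists numbering 34, the comparisons and the rule for naming genes were fixed before the data were examined. Lists were tested with camera in limma at its preset correlation, with an estimated correlation as the alternative, and with fry, adjusted over lists and both comparisons. Lists with fewer than 5 measured members were not tested. Named genes were Klf6 and Lyz2, the 10 highest and 10 lowest fold changes of each comparison with predicted and unnamed genes left out, and up to 4 members of each list with the largest changes past the test. Of these, 63 are given in the text, picked after their values were seen for what the genes are known to do. The lists in the text were likewise picked after their results were seen, and lists whose direction turned under another scaling in a comparison of genotypes were left out of it. The results of a few named genes, and a test that needs them, are not reported here.

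The same tests were checked on simulated counts with 200 genes changed by known folds, and on sets with no change. Alternatives were edgeR quasi-likelihood with TMM, DESeq2, other thresholds and filters on low values, another pseudocount, other scalings, each library left out in turn and the replicate number as a block. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. All 12 value columns were used. Exons of Klf6 could not be examined, since the deposited values are per gene.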

Results

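Total RNA from mouse bone marrow-derived macrophages was sequenced in 12 libraries that fall into 4 groups of 3. Bone marrow-derived macrophages are grown in culture from marrow progenitors. The cells came from Lyz2cre mice, which carry the Cre recombinase in the gene for lysozyme 2 and served as the control genotype, or from mice that in addition carried 2 floxed copies of Klf6 and are called Klf6-deleted here. Klf6 encodes a zinc-finger transcription factor of the Krüppel-like family. Cells of each genotype were left untreated or were given TNF, an inflammatory cytokine, at 10 ng/ml for 6 h. The series concerns macrophage KLF6 in experimental atherosclerosis, and the design asks how loss of Klf6 changes macrophage transcripts with and without TNF. The libraries held 16.9 to 23.4 M reads assigned to genes. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples. Values below are normalized read counts, given as mean ± SD with n = 3 libraries per group, and where a gene has a pair of values the Klf6-deleted group comes first. Fold changes compare Klf6-deleted with Lyz2cre cells on the log2(value + 1) scale, which understates the change of low genes.

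Klf6 itself was lower in Klf6-deleted cells in both conditions. In untreated cells it was at 7101 ± 269 against 10118 ± 174 normalized counts, a 1.43-fold difference, and in TNF-treated cells at 4161 ± 43.4 against 7447 ± 255, a 1.79-fold difference. The log2 change was -0.51 with a standard error of 0.0359 without TNF (limma, adjusted p = 7.1e-10) and -0.84 with a standard error of 0.0417 with TNF (limma, adjusted p = 4.3e-11). Every Klf6-deleted library lay below every Lyz2cre library of its table. Klf6 (ENSMUSG00000000078) lies on the plus strand of chromosome 13, from 5861482 to 5870394 in GRCm38. The labels do not say which exons are flanked by loxP sites, and a gene-level value also counts exons outside the deleted part. The reads that remained therefore show neither an intact transcript nor how far Klf6 was deleted. Lyz2, the gene that carries Cre, was also lower, at 244 ± 39.3 against 856 ± 26.5 without TNF and 931 ± 108 against 1656 ± 45.8 with TNF. Lyz2 has a near-identical neighbour, Lyz1, with which it can share reads, so its level is uncertain.

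**Figure D1:**
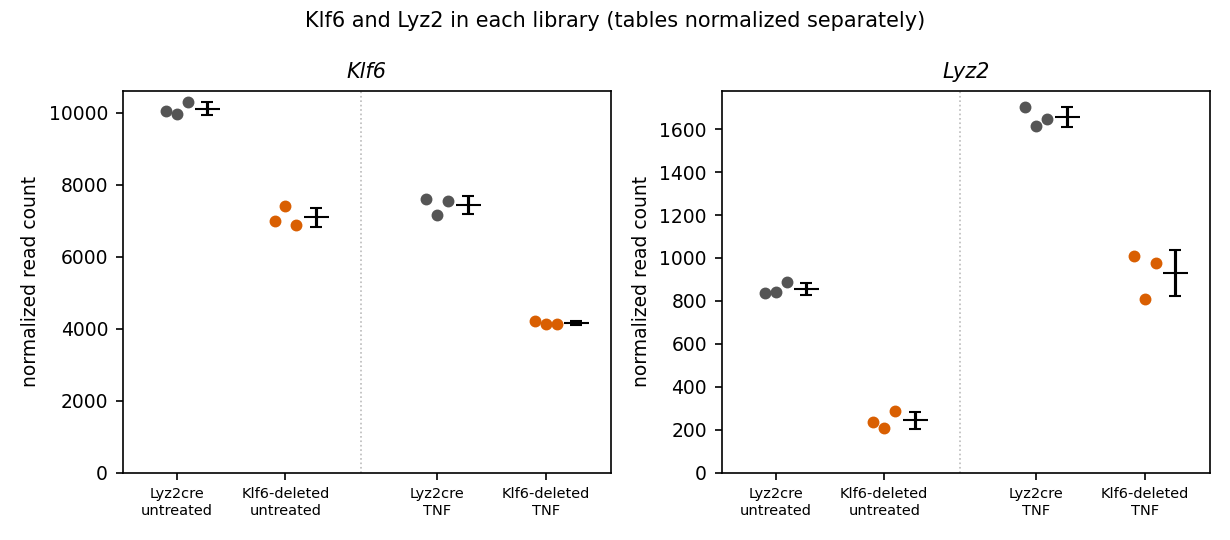
Normalized read counts of Klf6 (left) and Lyz2 (right) on linear axes from 0, with 1 point per library and the mean ± SD of 3 libraries beside the points. Grey points are Lyz2cre and orange points Klf6-deleted libraries, and the dotted line parts the untreated from the TNF table, which were normalized separately. Klf6 averaged 7101 in untreated Klf6-deleted and 10118 in untreated Lyz2cre libraries.

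Without TNF, Klf6-deleted cells carried higher transcripts of interferon-stimulated genes, glycolytic and hypoxia genes, cell cycle genes and stromal matrix genes. Their transcripts of macrophage identity genes, MHC class II genes and lysosomal genes were lower. These groups passed the set test with its preset correlation, and no list passed it with an estimated correlation (camera in limma, lowest adjusted p = 0.0841). Arg1, encoding the arginine-cleaving enzyme arginase 1, was among the 10 highest fold changes at 2791 ± 527 against 28.6 ± 3.89 normalized counts (n = 3 per group), 93.8-fold higher. Hpgd, whose enzyme inactivates prostaglandins, was among the 10 lowest at 26.0 ± 1.87 against 760.0 ± 18.7, 28.2-fold lower. The receptor for macrophage colony-stimulating factor, Csf1r, was 2.27-fold lower at 44591 ± 2582 against 101069 ± 498.

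Markers of stromal cells stood apart between the genotypes. All 18 of the 18 stromal markers measured were higher in untreated Klf6-deleted cells, with a median log2 change of 3.72, and adjusted over the list alone the count was also 18 (adjusted p = 0.162 with an estimated correlation). The collagen chain Col1a1 was at 16106 ± 673 against 571 ± 41.7, Col3a1 at 7816 ± 832 against 308 ± 63.2, and Cxcl12, a chemokine of marrow stroma, at 3977 ± 261 against 204 ± 42.1. Together the stromal markers made up 0.405% ± 0.0113 of the normalized counts in these cells and 0.0240% ± 0.00232 in Lyz2cre cells (n = 3 each). Of 13 monocyte markers, 11 were higher and 1 lower, the same counts as adjusted over the list alone (adjusted p = 0.132 with an estimated correlation). They included Plac8 at 604 ± 34.8 against 76.3 ± 31.5 and Vcan, encoding the matrix proteoglycan versican, at 1085 ± 215 against 60.9 ± 15.3. Of 8 endothelial markers, 7 were higher and none lower, also when adjusted over the list alone (adjusted p = 0.303 with an estimated correlation). Kdr, a receptor for vascular endothelial growth factor, was at 960.1 ± 119 against 387 ± 31.4. In the list of metalloproteinases and matrix genes, 18 of 24 were higher and 5 lower, also when adjusted over the list alone (adjusted p = 0.158 with an estimated correlation). The metalloproteinase inhibitor Timp3 was at 2205 ± 134 against 149 ± 28.7, and these rises stood beside that of the stromal markers.

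Interferon-stimulated genes were higher in Klf6-deleted cells without TNF. Of 41 measured, 37 were higher and none lower over all genes tested, and 38 were higher when adjusted over the list alone, with a median log2 change of 0.62 (adjusted p = 0.237 with an estimated correlation). The largest changes in the list were those of the interferon-inducible GTPases Iigp1, at 1506 ± 399 against 122 ± 9.56, and Gbp2, at 1785 ± 369.5 against 387 ± 50.3, and Irgm1 was at 3896 ± 426 against 1598 ± 72.7. Of 16 genes of MHC class I presentation, 14 were higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.188 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, was at 2520.4 ± 183 against 1049.8 ± 36.6. The glycolysis and hypoxia list had 28 higher and 1 lower of 30, also when adjusted over the list alone, with a median log2 change of 0.89 (adjusted p = 0.0841 with an estimated correlation). Adm, encoding the vasodilator peptide adrenomedullin, was at 333 ± 14.2 against 36.9 ± 7.95, the prolyl hydroxylase genes Egln3 at 349 ± 21.2 against 77.8 ± 7.65 and P4ha2 at 1019 ± 68.4 against 157 ± 12.0. The 1 member that was lower was Ndrg1, a gene induced by hypoxia, at 695 ± 38.7 against 1886 ± 117. Of 38 cell cycle genes, 36 were higher and 1 lower, also when adjusted over the list alone, with a median log2 change of 1.11 (adjusted p = 0.132 with an estimated correlation). Bub1, a kinase of the spindle checkpoint, was at 188 ± 8.68 against 52.4 ± 11.2 and the mitotic kinesin Kif20a at 266 ± 20.8 against 83.5 ± 6.43. Of 33 immediate early and stress genes, 23 were higher and 8 lower, also when adjusted over the list alone (adjusted p = 0.237 with an estimated correlation), with Ddit4, an inhibitor of the growth kinase complex mTORC1, at 282 ± 10.7 against 51.4 ± 5.02. Cd5l, a secreted macrophage protein, reached 37769 ± 865 against 6004 ± 201. Each of these gene groups moved with genotype in the same libraries as the stromal markers above.

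Macrophage identity genes were lower in the same cells, beside the higher stromal markers. Of 21 measured, 18 were lower and 2 higher, also when adjusted over the list alone, with a median log2 change of -0.41 (adjusted p = 0.291 with an estimated correlation). Mertk, a receptor for apoptotic cells, was at 1561 ± 29.6 against 3317 ± 154. Of 13 MHC class II and co-stimulation genes, 10 were lower and 1 higher, also when adjusted over the list alone (adjusted p = 0.237 with an estimated correlation), with the invariant chain Cd74 at 12759 ± 675 against 33146 ± 1569.8 and the class II chain H2-Ab1 at 3669.6 ± 114 against 8873 ± 223. Of 34 lysosome and autophagy genes, 25 were lower and 7 higher, also when adjusted over the list alone (adjusted p = 0.291 with an estimated correlation). The protease gene Ctsc was at 7981 ± 799 against 15460.3 ± 359.9 and Tfeb, a transcription factor for lysosomal genes, at 1009 ± 40.8 against 1783 ± 79.4. Of 25 efferocytosis and complement genes, 15 were lower and 7 higher, also when adjusted over the list alone (adjusted p = 0.475 with an estimated correlation), and the median log2 change was -0.39 while the mean was -0.02. In the cholesterol biosynthesis list 13 of 24 were lower and 2 higher, also when adjusted over the list alone (adjusted p = 0.643 with an estimated correlation). That list's set test passed with all libraries (camera in limma, adjusted p = 0.0305) and not without Klf6-deleted replicate 2 (camera in limma, adjusted p = 0.0610). Of 33 NF-kB and TNF response genes, 20 were lower and 9 higher, also when adjusted over the list alone (adjusted p = 0.503 with an estimated correlation), with Birc3 at 751 ± 52.6 against 1777 ± 56.0 and Cd83 at 764 ± 11.1 against 2149 ± 156. The set test of this list did not pass with all libraries (camera in limma, adjusted p = 0.0738) and passed without Klf6-deleted replicate 3 (camera in limma, adjusted p = 0.0378). Its median log2 change was -0.32 and its mean 0.01, and scaled to total reads its median was -0.19, with 17 lower and 9 higher. The inhibitory Fc receptor Fcgr2b, at 1337 ± 359 against 7176 ± 339, and the haemoglobin scavenger receptor Cd163, at 324 ± 31.6 against 1442 ± 61.1, were also lower. Transcripts of Eps8l1, a relative of the actin regulator Eps8, were near 0 in Klf6-deleted cells at 1.63 ± 2.14 against 321 ± 12.9.

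In all, 12715 genes were tested without TNF, of which 7230 changed (limma, adjusted p below 0.05), 3508 of them higher and 3722 lower in Klf6-deleted cells. A change of at least 2-fold was found for 1408 higher and 345 lower genes. Klf6-deleted cells had a lower sum of normalized counts (19.0 M on average, against 20.8 M), so scaling to total reads raised the median of all genes by 0.13 on the log2 scale and gave 5121 higher and 2408 lower genes, a share of 68.0% higher in place of 48.5%. The medians of the lists described kept their sign under that scaling, since lists that turned were left out. Those left out include cholesterol efflux and LXR target genes (median log2 change -0.08, scaled 0.05). Under that scaling 13 macrophage identity genes were lower and 3 higher, and 21 lysosome and autophagy genes were lower and 8 higher. The set test (camera in limma, with its preset correlation) passed for 16 of 33 lists measured, 10 with higher and 6 with lower members. With an estimated correlation it passed for 0 lists, while 8 had an unadjusted p below 0.05, and fry in limma, which asks whether a list moves on balance in 1 direction, passed for 26.

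**Figure D2:**
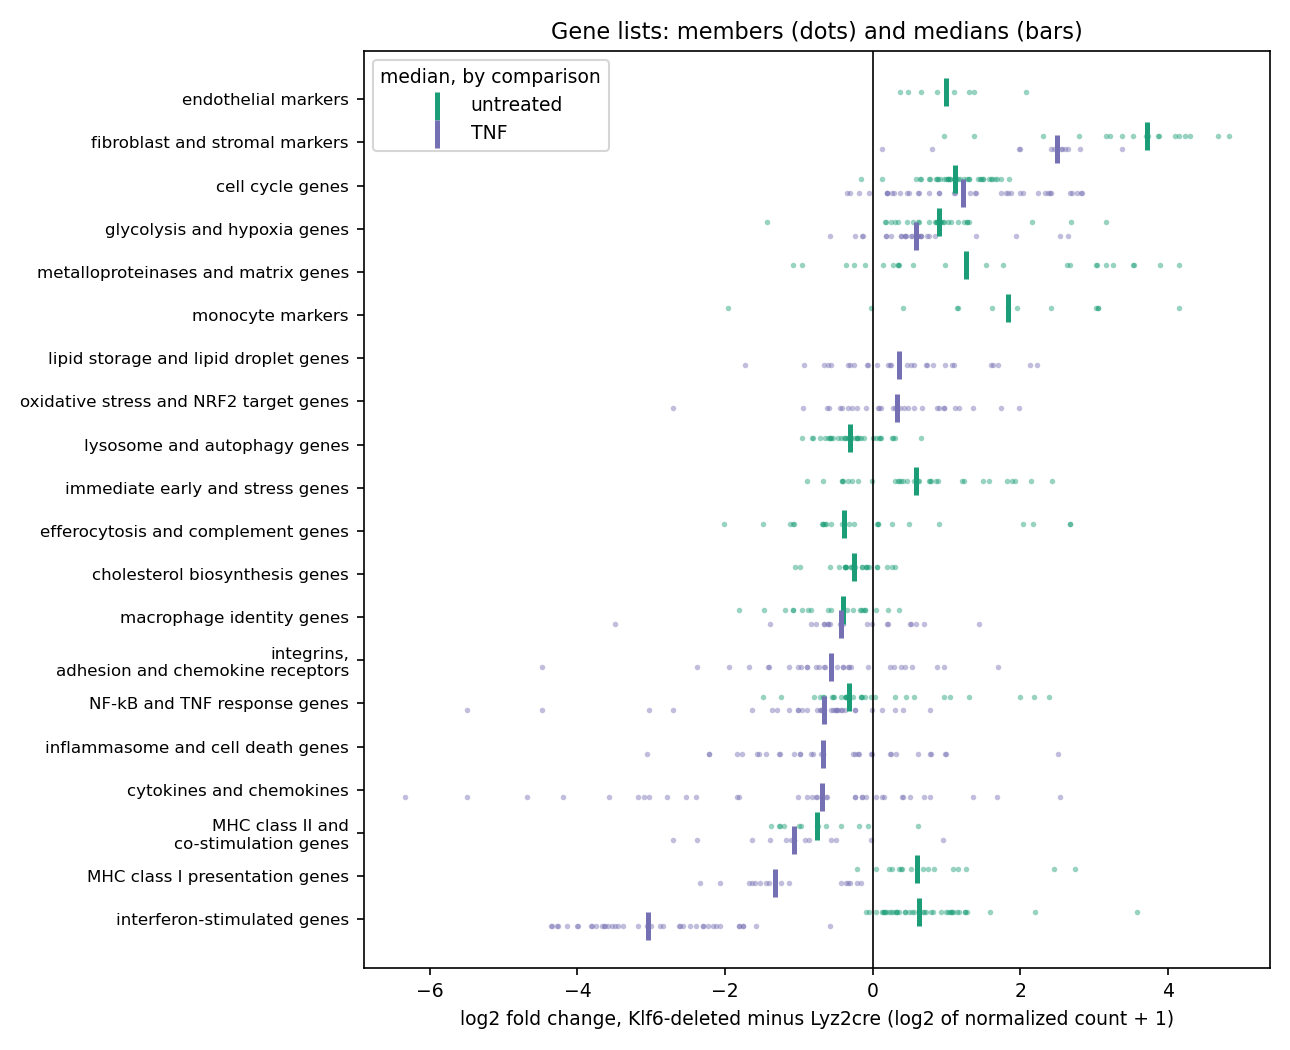
Log2 fold changes (Klf6-deleted minus Lyz2cre, of normalized counts + 1) of the members of each list described for a comparison, as dots, with the median as a bar. Green stands for the untreated and purple for the TNF comparison, and a list is drawn for a comparison only where the text describes it there. Interferon-stimulated genes had medians of 0.62 without and -3.05 with TNF.

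With TNF, Klf6-deleted cells had lower transcripts of interferon-stimulated genes, antigen presentation genes and 22 of 36 cytokines and chemokines than Lyz2cre cells, and higher transcripts of glycolytic, cell cycle and lipid storage genes. Here too no list passed the set test with an estimated correlation (camera in limma, lowest adjusted p = 0.0841). Cxcl10, a chemokine that attracts T cells, was at 547 ± 47.2 against 24878 ± 3907 normalized counts (n = 3 per group), 45.1-fold lower. The adhesion molecule Vcam1 was 22.2-fold lower at 412 ± 10.9 against 9204 ± 647, and Ch25h, whose enzyme makes 25-hydroxycholesterol, was 44.2-fold lower at 136 ± 18.5 against 6099 ± 1024. Hmox1, encoding the haem-degrading enzyme haem oxygenase 1, was 2.56-fold higher at 48732 ± 1331 against 19067 ± 1616.

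All 41 interferon-stimulated genes measured were lower in TNF-treated Klf6-deleted cells, also when adjusted over the list alone, with a median log2 change of -3.05 (adjusted p = 0.237 with an estimated correlation). Ifit2 was at 2775 ± 165 against 56891 ± 5773 and Mx1 at 738 ± 22.98 against 14248 ± 1888, both antiviral effectors. Of 33 NF-kB and TNF response genes, 27 were lower and 3 higher over all genes tested, against 28 and 3 adjusted over the list alone (adjusted p = 0.291 with an estimated correlation). Cd40, the co-stimulatory receptor, was at 1209 ± 103 against 7915 ± 685 and the chemokine Ccl5 at 2209 ± 250.2 against 18107 ± 2719, while Birc3 was at 5589 ± 124 against 9051 ± 171. Of 36 cytokines and chemokines, 22 were lower and 8 higher, against 24 and 8 adjusted over the list alone (adjusted p = 0.436 with an estimated correlation), with Cxcl11 at 8.34 ± 6.25 against 672 ± 177 and the anti-inflammatory cytokine Il10 at 7.79 ± 1.17 against 161 ± 29.8. The death ligand gene Tnfsf10 was at 92.4 ± 16.8 against 2878 ± 433. All 16 MHC class I presentation genes were lower, also when adjusted over the list alone (adjusted p = 0.301 with an estimated correlation), with Nlrc5 at 1689 ± 79.0 against 8545 ± 903 and the peptide transporter Tap1 at 3766 ± 254 against 15793 ± 1371. Of 14 MHC class II and co-stimulation genes, 12 were lower and 1 higher, also when adjusted over the list alone (adjusted p = 0.303 with an estimated correlation), with Cd86 at 109 ± 7.02 against 575 ± 83.5 and Cd74 at 3780.2 ± 181 against 9903 ± 817. Of 33 inflammasome and cell death genes, 21 were lower and 8 higher, against 22 and 8 adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). The caspase of the non-canonical inflammasome, Casp4, was at 328 ± 12.3 against 2740.3 ± 136 and the necroptosis effector Mlkl at 498 ± 12.0 against 2326 ± 200.2. Of 30 integrins, adhesion molecules and chemokine receptors, 20 were lower and 6 higher, against 20 and 7 adjusted over the list alone (adjusted p = 0.146 with an estimated correlation), with the junctional adhesion molecule F11r at 30.0 ± 7.39 against 158 ± 22.96. The RNA sensor Tlr3 was at 332 ± 15.7 against 2115 ± 293, and the IgG receptor Fcgr1 was at 695 ± 48.0 against 7865 ± 1424.

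Among the higher groups, the glycolysis and hypoxia list had 24 higher and 4 lower of 29, against 25 and 4 adjusted over the list alone (adjusted p = 0.132 with an estimated correlation). Egln3 was at 793 ± 50.3 against 136 ± 14.8 and Vegfa, the vascular endothelial growth factor gene, at 2959.9 ± 134 against 1123 ± 53.9. Of 38 cell cycle genes, 29 were higher and 1 lower, also when adjusted over the list alone, with a median log2 change of 1.22 (adjusted p = 0.0841 with an estimated correlation). The cyclin gene Ccna2 was at 86.1 ± 11.7 against 12.0 ± 3.43 and Birc5, encoding survivin, at 62.4 ± 18.4 against 9.06 ± 5.92. Of 28 lipid storage genes, 16 were higher and 6 lower, also when adjusted over the list alone (adjusted p = 0.237 with an estimated correlation). The fatty acid binding protein gene Fabp4 was at 687 ± 60.3 against 149 ± 32.6, while Acsl1, which activates long-chain fatty acids, was lower, at 9439 ± 274 against 31402 ± 485. Of 31 oxidative stress and NRF2 target genes, 18 were higher and 9 lower, against 19 and 9 adjusted over the list alone (adjusted p = 0.477 with an estimated correlation). The quinone reductase gene Nqo1 was at 297 ± 12.2 against 76.2 ± 19.6, while Nos2, the inducible nitric oxide synthase gene, was lower, at 297 ± 16.1 against 1979.8 ± 483. The desaturase gene Scd2 was at 941 ± 54.8 against 86.4 ± 15.6, Cd5l at 14075 ± 646 against 1071 ± 47.8, Arg1 at 1144 ± 21.7 against 113 ± 12.8, Cpt1c, of the carnitine palmitoyltransferase family, at 76.2 ± 10.3 against 2.77 ± 2.95 and Nbea, encoding the trafficking protein neurobeachin, at 78.2 ± 7.80 against 2.04 ± 2.06. Klf2, a member of the same family as Klf6 that restrains NF-kB activity in macrophages, was 3.41-fold higher at 2522 ± 129.7 against 738 ± 45.4. Stromal markers were also higher with TNF, with 12 of 13 past the test and none lower, also when adjusted over the list alone (adjusted p = 0.303 with an estimated correlation). They made up 0.0291% ± 0.00217 of the normalized counts in Klf6-deleted and 0.00463% ± 0.00117 in Lyz2cre cells (n = 3 each), and this rise stood beside every gene group described for TNF. Eps8l1 was at 0.926 ± 0.934 against 203 ± 7.72.

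In all, 11717 genes were tested with TNF, of which 6711 changed (limma, adjusted p below 0.05), 3103 of them higher and 3608 lower in Klf6-deleted cells. A change of at least 2-fold was found for 953 higher and 814 lower genes. The sum of normalized counts was again lower in Klf6-deleted cells (16.4 against 20.6 M on average), so scaling to total reads raised the median of all genes by 0.33 on the log2 scale and gave 7038 higher and 1716 lower genes, a share of 80.4% higher in place of 46.2%. The medians of the lists described kept their sign under that scaling, since lists that turned were left out. Those left out include ribosomal protein genes (median log2 change -0.12, scaled 0.20) and oxidative phosphorylation genes (-0.11, scaled 0.21). In some lists described fewer genes were lower, 18 with 14 higher for cytokines and chemokines (median log2 change -0.37), and 11 with 1 higher for MHC class I presentation genes. For integrins, adhesion molecules and chemokine receptors they were 15 lower and 9 higher (median -0.24), and for inflammasome and cell death genes 18 and 12 (median -0.35). With TMM, 15 MHC class I presentation genes were lower. Lyz2cre replicate 2 with TNF stood apart from its group, with a chi-square per gene of 9.48 and 7.02 against the other replicates, which had 3.09 between them. Interferon-stimulated genes took 3.01% of its normalized counts, against 3.44% and 3.41% in the others. Without it, 6619 genes changed and the median log2 change of the interferon-stimulated genes was -3.09. The set test (camera in limma, with its preset correlation) passed for 13 of 30 lists measured, 5 with higher and 8 with lower members. With an estimated correlation it passed for 0 lists, while 4 had an unadjusted p below 0.05, and fry in limma, which asks whether a list moves on balance in 1 direction, passed for 24.

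**Figure D3:**
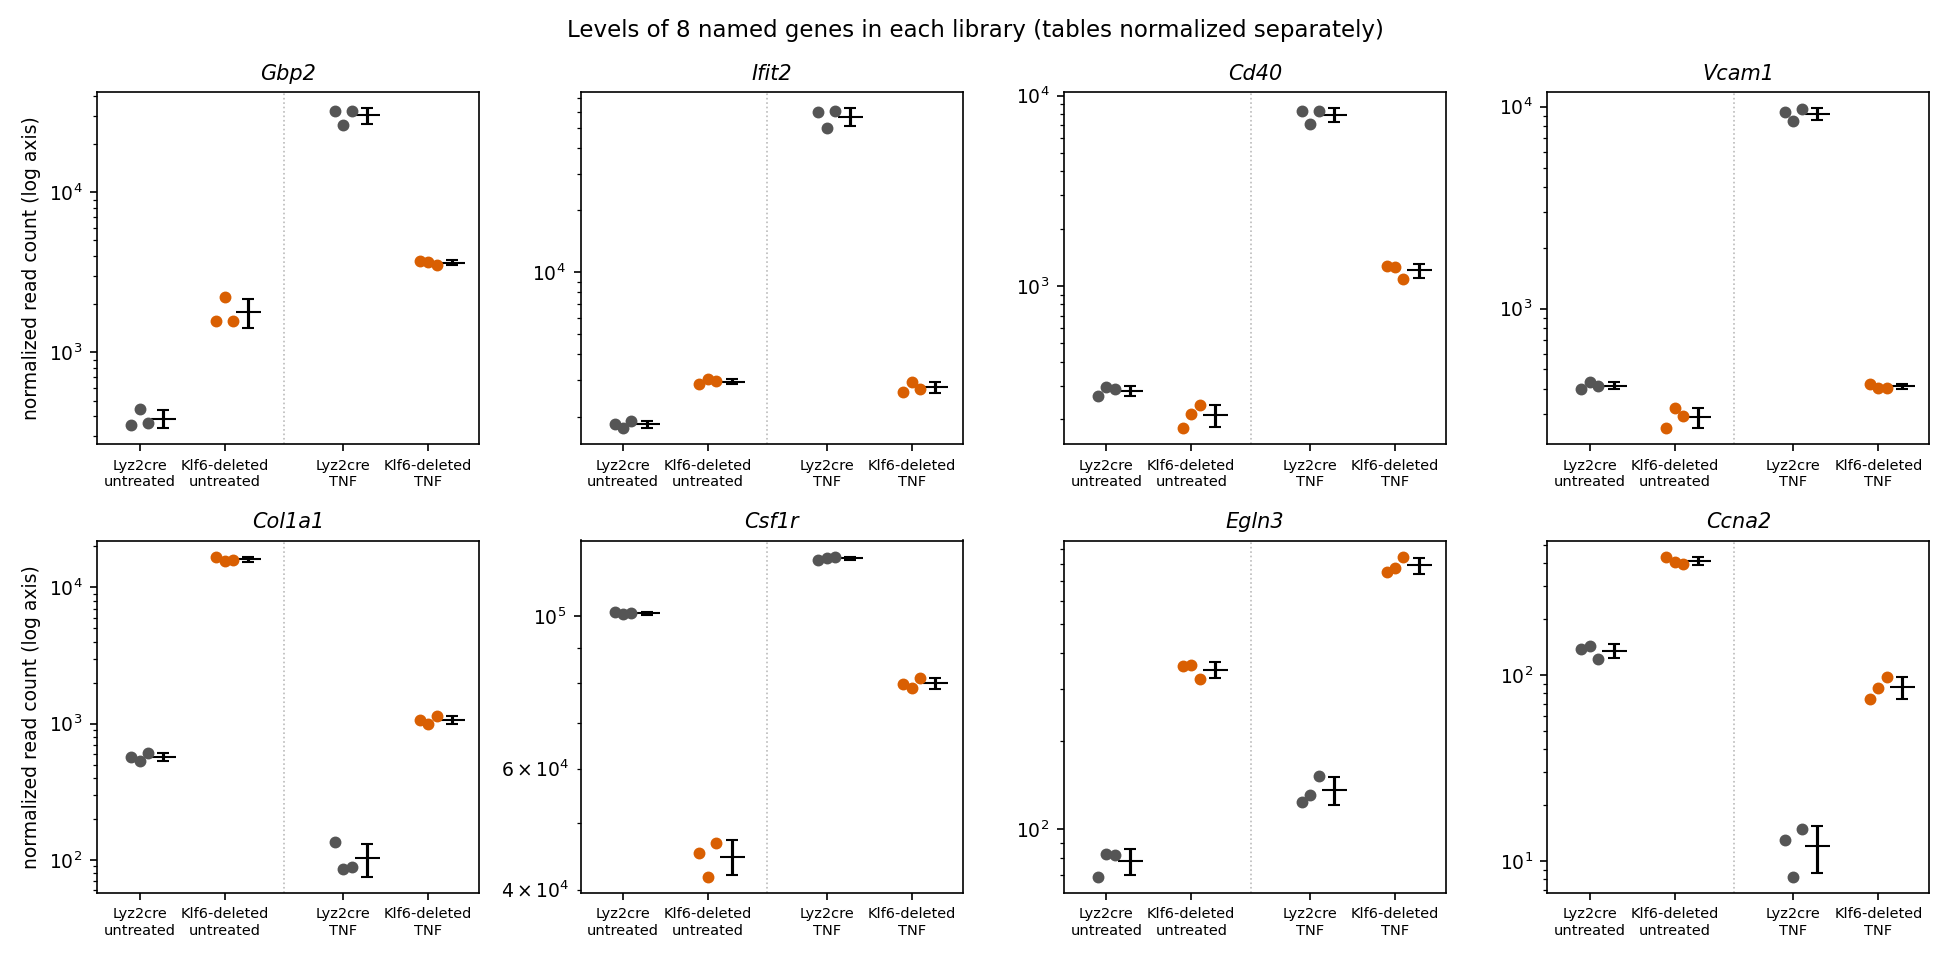
Normalized read counts of 8 named genes on log axes, with 1 point per library and the mean ± SD of 3 libraries beside the points. Grey points are Lyz2cre and orange points Klf6-deleted libraries, and the dotted line parts the untreated from the TNF table, which were normalized separately. With TNF, Gbp2 averaged 3632 in Klf6-deleted and 30168 in Lyz2cre libraries, and without TNF 1785 and 387.

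The effect of Klf6 deletion on interferon-stimulated genes had opposite directions in the 2 conditions. The difference between the effect with TNF and the effect without it was negative for all 41 of these genes, also when adjusted over the list alone, with a median of -3.74 on the log2 scale (adjusted p = 0.0828 with an estimated correlation). Gbp2 was 4.57-fold higher without TNF and 8.27-fold lower with it, a difference of -5.24 on the log2 scale with a standard error of 0.151 (limma, adjusted p = 4.9e-16). Iigp1 was 12.0-fold higher and 12.3-fold lower, a difference of -7.20 with a standard error of 0.235 (limma, adjusted p = 3.1e-15). Of 16 MHC class I presentation genes, 15 had a negative difference and none a positive one, also when adjusted over the list alone (adjusted p = 0.0904 with an estimated correlation). Of 32 integrins, adhesion molecules and chemokine receptors, 21 had a negative and 3 a positive difference, against 21 and 4 adjusted over the list alone. At the scaling reported, this was the 1 list whose set test also passed with an estimated correlation (adjusted p = 0.0401). Scaled to total reads, a setting chosen after seeing the data, more lists passed, among them interferon-stimulated genes (camera in limma with an estimated correlation, adjusted p = 0.0332). Of 21 macrophage identity genes, 14 had a positive and 4 a negative difference, against 16 and 4 adjusted over the list alone (adjusted p = 0.271 with an estimated correlation). With TNF, however, 12 of them were lower and 7 higher in Klf6-deleted cells, also when adjusted over the list alone, with a median log2 change of -0.43 beside -0.41 without TNF (adjusted p = 0.643 with an estimated correlation). Their set test with TNF did not pass (camera in limma, adjusted p = 0.117), and scaled to total reads 10 were lower and 9 higher with TNF, with medians of -0.11 with and -0.28 without it. Csf1r was 2.27-fold lower without and 1.52-fold lower with TNF, while Mertk was 2.12-fold lower without and 1.43-fold higher with it. Of 14 MHC class II and co-stimulation genes, 5 had a negative and 3 a positive difference, against 6 and 3 adjusted over the list alone (adjusted p = 0.6001 with an estimated correlation). Their set test did not pass (camera in limma, adjusted p = 0.182) while fry in limma did (adjusted p = 0.00133). The difference of Cd86 was -1.13 with a standard error of 0.162 (limma, adjusted p = 9.1e-06) and that of Cd74 -0.01 with a standard error of 0.0776 (limma, adjusted p = 0.931). Scaled to total reads, 5 of the list had a negative and 5 a positive difference, and that of Cd74 was 0.19 (limma, adjusted p = 0.0355).

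Across all genes, 6392 of 13062 had an effect of Klf6 deletion that differed between the conditions (limma, adjusted p below 0.05), 3145 with a more positive and 3247 with a more negative effect with TNF. Scaling to total reads shifted the median difference by 0.19 and gave 4930 more positive and 2196 more negative genes, a share of 69.2% in place of 49.2%. The 2 comparisons share no library. Genes are not independent replicates, so the p-values of the overlaps below do not measure the spread between samples. Among the 11425 genes tested in both, 1179 were higher in both, where independent lists would share 758 (Fisher's exact test, two-sided, odds ratio 2.55, p = 3.6e-89), and 1530 were lower in both, against 1086 (odds ratio 2.28, exact p = 2.9e-82). Genes higher without and lower with TNF numbered 788, against 863 (odds ratio 0.844, exact p = 3.8e-04). Among genes changed at least 1.5-fold this overlap turned to an excess (219 shared, odds ratio 1.68), and without Klf6-deleted replicate 2 it did not pass (odds ratio 0.928, exact p = 0.142). Genes lower without and higher with TNF numbered 747, against 953 (odds ratio 0.638, exact p = 1.6e-21), and among genes changed at least 1.5-fold this overlap did not pass (odds ratio 0.855, exact p = 0.140). Across genes, which are not independent replicates, the log2 changes of the 2 comparisons had a Pearson correlation of 0.341 and a Spearman correlation of 0.217.

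**Figure D4:**
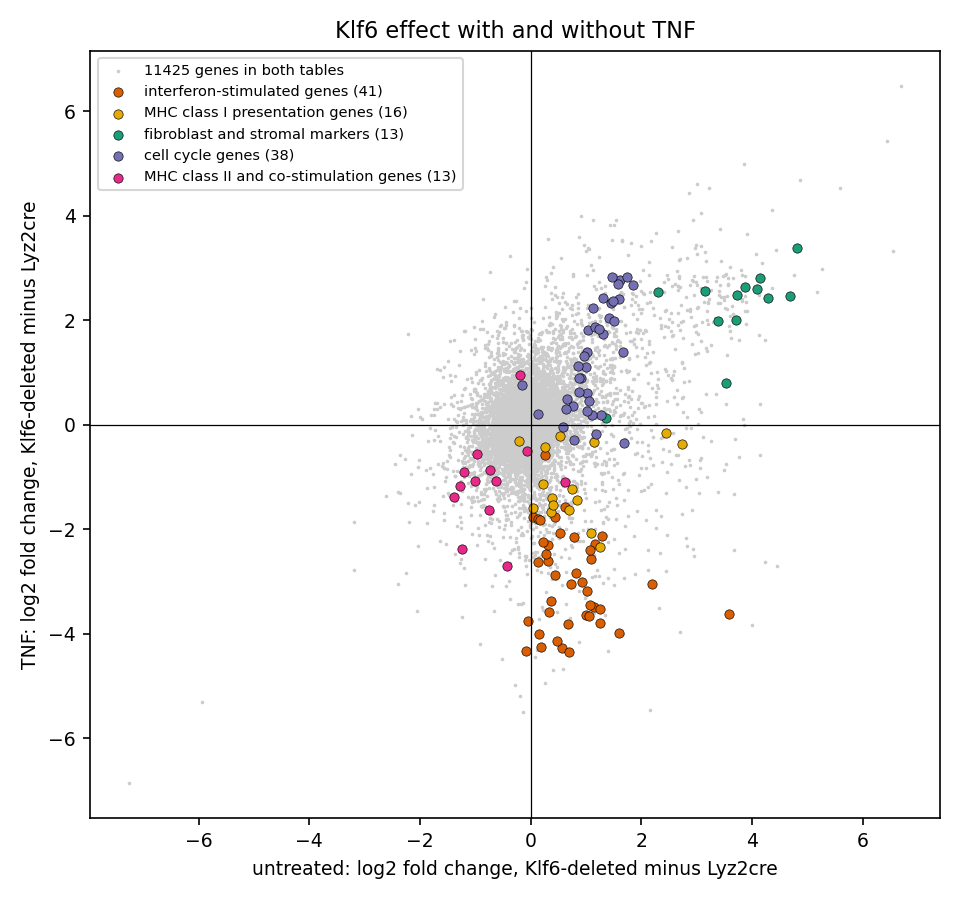
Log2 fold changes (Klf6-deleted minus Lyz2cre, of normalized counts + 1) without TNF on the x axis and with TNF on the y axis. Grey dots are the 11425 genes tested in both tables and coloured dots are members of 5 lists, with the number drawn in the legend. All 41 interferon-stimulated genes lie below 0 on the y axis, and all 13 stromal markers drawn lie above 0 on both axes.

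The response to TNF was set side by side from levels in separately normalized tables, and these ratios were not tested. A joint edgeR fit of the recovered reads, chosen after seeing the data, called 1645 genes at least 2-fold higher and 2662 lower with TNF in Lyz2cre cells, and 787 and 2189 in Klf6-deleted cells (edgeR, adjusted p below 0.05). In Lyz2cre cells, Gbp2 rose from 387 ± 50.3 to 30168 ± 3359 and Vcam1 from 417 ± 17.6 to 9204 ± 647. In Klf6-deleted cells, Gbp2 stood at 1785 ± 369.5 and 3632 ± 123 and Vcam1 at 291 ± 32.8 and 412 ± 10.9. Birc3, an inhibitor of apoptosis induced by NF-kB, stood at 1777 ± 56.0 and 9051 ± 171 in Lyz2cre cells and at 751 ± 52.6 and 5589 ± 124 in Klf6-deleted cells. Across these tables, 1170 genes were at least 2-fold higher and 3083 at least 2-fold lower with TNF in Lyz2cre cells, and 564 and 2748 in Klf6-deleted cells. These counts depend on the scale between the tables, as the median log2 ratio was -0.32 in Lyz2cre and -0.29 in Klf6-deleted cells. With ratios recentred on that median, the counts were 1583 higher and 2270 lower in Lyz2cre cells, and 767 and 2110 in Klf6-deleted cells. Stromal levels were lower in the TNF table in both genotypes, with Col1a1 at 571 ± 41.7 and 104 ± 28.3 in Lyz2cre cells and at 16106 ± 673 and 1067 ± 75.4 in Klf6-deleted cells.

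Genes that rose with TNF in Lyz2cre cells were mostly lower in TNF-treated Klf6-deleted cells. Of the 1168 genes tested that were at least 2-fold higher with TNF in Lyz2cre cells, 920 (78.8%) were lower in Klf6-deleted cells and 91 were higher. Of the 10375 other genes, 25.9% were lower (Fisher's exact test, two-sided, odds ratio 10.6, p = 1.5e-276). Genes are not independent replicates, so this p-value does not measure the spread between samples. The median log2 change of the TNF-responsive genes was -0.91. Both measures use the Lyz2cre TNF libraries, so a part of this could come from the selection of genes. In 20 simulations with no effect of genotype, chosen after the results were seen, the genes were selected anew each time (1148 to 1175 genes) and their median log2 change lay between -0.0102 and 0.00145. These simulations took the Lyz2cre TNF means as true for both genotypes and drew only the spread between libraries. A deviation shared by all Lyz2cre TNF libraries was therefore not sized, and that part of the selection stays open. When the response was taken from Klf6-deleted cells in place of Lyz2cre cells, 335 of 549 responsive genes (61.0%) were lower. Scaling to total reads was not run for these shares.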

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

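The tests of single explanations in this part, and the counts of other splits of the libraries, were chosen after the results were seen. The test of the difference between the effects of Klf6 deletion with and without TNF was planned. What drew attention here was such a difference past its test (limma over the 4 groups, adjusted p below 0.05), which was found for 56 of the 63 named genes. Over all genes it was found for 6392 of 13062 (48.9%). Named genes were picked for large changes in a condition, which favours such a difference, so their count is no result about them. By the set test of the difference (camera in limma, preset correlation), 14 of the 20 lists described passed, and 1 of them passed with an estimated correlation. Scaled to total reads, more of them passed with an estimated correlation, as given below. Differences are given below as the log2 effect with TNF minus that without, with n = 3 libraries in each of 4 groups. Stromal markers moved with genotype in the same libraries.

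Among interferon-stimulated, antigen presentation and co-stimulation genes, negative differences were -7.20 for Iigp1, -5.24 for Gbp2, -3.41 for Irgm1, -5.04 for Ifit2, -4.44 for Mx1, -3.59 for Nlrc5, -3.15 for Tap1 and -1.13 for Cd86. Among secreted proteins they were -5.35 for Cxcl10, -6.27 for Cxcl11, -4.33 for Ccl5, -3.28 for Il10 and -5.20 for Tnfsf10, and -1.88 for Cxcl12. For receptors and adhesion molecules they were -3.95 for Vcam1, -2.27 for Cd40, -4.09 for F11r, -3.69 for Fcgr1, -3.10 for Tlr3 and -3.19 for Kdr. For enzymes of lipid, arginine and nitric oxide metabolism they were -7.62 for Ch25h, -1.79 for Acsl1, -3.22 for Arg1 and -5.53 for Nos2, and for the cell death genes -1.87 for Casp4 and -3.37 for Mlkl. Ch25h, whose product 25-hydroxycholesterol is an antiviral oxysterol, was at 28.6 ± 8.94 against 5.74 ± 2.37 normalized counts without TNF. Its difference thus rests in part on these low untreated levels, while with TNF it was lower in Klf6-deleted cells.

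The matrix genes had differences of -1.44 for Col1a1, -2.22 for Col3a1 and -1.54 for Timp3. The monocyte markers Vcan and Plac8 had -4.73 and -2.74, but of 13 monocyte markers 6 had a negative and 4 a positive difference, against 7 and 4 adjusted over the list alone (adjusted p = 0.448 with an estimated correlation), and the set test did not pass (camera in limma, adjusted p = 0.220). The stress gene Ddit4 had -1.37 and the protease gene Ctsc -0.49. The targeted gene Klf6 was lowered further with TNF, with a difference of -0.33, or -0.13 when scaled to total reads (limma, adjusted p = 0.0357), and Lyz2 less, with 0.98. Among genes that were lower in Klf6-deleted cells without TNF, positive differences were 0.58 for Csf1r, 1.60 for Mertk, 2.32 for Cd163, 1.70 for Fcgr2b, 0.63 for Tfeb and 0.55 for Birc3. Positive differences were also 1.06 for Cd5l, 1.66 for Fabp4, 2.48 for Scd2 and 1.62 for Cpt1c, which concern lipid handling, and 1.14 for Hmox1 and 1.20 for Nqo1, which are targets of the stress factor NRF2. Of 30 glycolysis and hypoxia genes, 20 had a negative and 5 a positive difference, also when adjusted over the list alone (adjusted p = 0.0904 with an estimated correlation). Its named members had -2.51 for Adm, 0.39 for Egln3, 0.54 for Vegfa and 1.96 for Ndrg1, while P4ha2, with -0.05, was not past the test (limma, adjusted p = 0.793). Of 38 cell cycle genes, 15 had a positive and 8 a negative difference, against 15 and 9 adjusted over the list alone (adjusted p = 0.822 with an estimated correlation), and the set test did not pass (camera in limma, adjusted p = 0.768). Bub1, Ccna2 and Birc5 had 0.83, 1.16 and 1.35, while Kif20a, with -0.26, was not past the test (limma, adjusted p = 0.361). Klf2 had 1.18. The highest adjusted p among the named genes past the test was that of Egln3 (limma, adjusted p = 0.0484).

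Adm and Hpgd lay below the filter on low values with TNF, and Cxcl11 and Nos2 without it, so their differences rest on low levels in 1 table. Hpgd had a difference of 2.63, with 0.311 against 4.93 normalized counts with TNF, which does not show a smaller effect there. Its difference did not pass by edgeR (1.26, edgeR, adjusted p = 0.680) or with a pseudocount of 0.1 (0.43, limma, adjusted p = 0.754). Nor did that of Egln3 (edgeR, adjusted p = 0.0749, and limma, adjusted p = 0.0506). That of Cxcl11 did not pass by edgeR (edgeR, adjusted p = 0.179) and that of Cxcl12 not with a pseudocount of 0.1 (limma, adjusted p = 0.0544). All other named genes past the test passed both ways, and all named genes past the test kept direction and call when scaled to total reads.

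Lists differed too, given as the median difference of their members. The negative medians were -3.74 for interferon-stimulated genes (adjusted p = 0.0828 with an estimated correlation), -1.96 for MHC class I presentation genes (adjusted p = 0.0904 with an estimated correlation) and -1.58 for cytokines and chemokines (adjusted p = 0.0904 with an estimated correlation). They were also -1.40 for fibroblast and stromal markers (adjusted p = 0.124 with an estimated correlation), -1.16 for metalloproteinases and matrix genes (adjusted p = 0.0904 with an estimated correlation) and -0.69 for integrins, adhesion and chemokine receptors (adjusted p = 0.0401 with an estimated correlation). Smaller ones were -0.47 for inflammasome and cell death genes (adjusted p = 0.0904 with an estimated correlation), -0.38 for NF-kB and TNF response genes (adjusted p = 0.159 with an estimated correlation) and -0.38 for immediate early and stress genes (adjusted p = 0.0904 with an estimated correlation). The least negative was -0.29 for glycolysis and hypoxia genes (adjusted p = 0.0904 with an estimated correlation). The positive medians were 0.35 for lipid storage and lipid droplet genes (adjusted p = 0.132 with an estimated correlation), 0.31 for lysosome and autophagy genes (adjusted p = 0.0904 with an estimated correlation) and 0.27 for oxidative stress and NRF2 target genes (adjusted p = 0.271 with an estimated correlation). The last was 0.27 for macrophage identity genes (adjusted p = 0.271 with an estimated correlation). Scaled to total reads, all these medians kept their sign, with -0.10 for glycolysis and hypoxia genes (14 negative and 7 positive). They were -0.18 for NF-kB and TNF response and for immediate early and stress genes, and -0.28 for inflammasome and cell death genes. The positive medians rose, and ran from 0.46 for macrophage identity to 0.54 for lipid storage genes. For lipid storage and lipid droplet genes the set test did not pass (camera in limma, adjusted p = 0.0557). With an estimated correlation it passed for interferon-stimulated, MHC class I, cytokine, inflammasome, immediate early, metalloproteinase and integrin lists (camera in limma, adjusted p from 0.0128 to 0.0495).

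Other splits of the same libraries were counted for each model. Untreated, 1 of the 10 splits of 6 libraries into 3 and 3 gave as many changed genes, the real one, with 7230 by limma against at most 0 in the others, where at most 122 genes had an unadjusted p below 0.05. With TNF it was again 1 of 10, with 6711 against at most 0, and at most 130 at an unadjusted p below 0.05. Such designs have too few splits for a share under 0.05. For the difference between the effects, where more splits exist than were run, 100 were taken, the real one and 99 drawn at random. Of these 100, 1 gave as many genes, the real one, with 6392 against at most 2689. A split that mixes the genotypes puts their differences into the spread within groups, so few calls were likely there beforehand. These counts therefore exclude neither chance nor a difference between cultures or animals that runs along with genotype. The splits with many genes were among the 13 that kept the real grouping in 1 table, and the others gave at most 1 gene.

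Stromal transcripts were higher and macrophage transcripts lower in untreated Klf6-deleted libraries, with Col1a1 at 16106 ± 673 against 571 ± 41.7 normalized counts and Csf1r at 44591 ± 2582 against 101069 ± 498 (n = 3 each). Fewer macrophages alone would lower the macrophage identity genes by 1 common factor. Of the 21, 18 were lower and 2 higher (limma, adjusted p below 0.05), so not all fell by 1 factor. The log2 changes ran from -1.82, that of Lyz2, whose level is uncertain, to 0.35. While 19 lay more than 3 standard errors from their median of -0.41, these errors hold only the spread between these libraries. No other list was set beside this count, so it does not exclude a lower share of macrophages together with other changes. Stromal cells in the cultures would also raise collagen genes outside the fixed marker list, and 77.3% of 22 were higher (17) with 0 lower (limma, adjusted p below 0.05), which lies between the bounds of 80% and 50% set for a verdict. Of the 18 markers measured, 15 were at 20 or more normalized counts in Lyz2cre cells as well and 11 reached 1000 in Klf6-deleted cells, and no other list holds them. More stromal cells and stromal transcripts made by Klf6-deleted macrophages therefore cannot be told apart, since bulk libraries do not say which cells made a transcript, and both may contribute.

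Interferon-stimulated genes were lower in TNF-treated Klf6-deleted libraries, with Ifit2 at 2775 ± 165 against 56891 ± 5773 normalized counts (n = 3 each). The scale of the libraries was argued against, as the highest median log2 change over 3 scalings was -2.72, and so was a lower share of macrophages, as the macrophage identity genes had a median 2.61 higher on the log2 scale. Swapped genotype labels were argued against because in 3 of 3 Klf6-deleted TNF libraries Klf6 lay below every Lyz2cre TNF library. Klf6 was lower in Klf6-deleted libraries without TNF as well, so it cannot check the treatment labels. A candidate explanation that stays open is less interferon beta, the cytokine encoded by Ifnb1, picked after its values were seen, whose transcript had a log2 change of -4.13 with a standard error of 0.579 (limma, adjusted p = 1.4e-05). It had 74 reads in the 3 Lyz2cre and 2 in the 3 Klf6-deleted libraries with TNF, a ratio of 41.6 (95% exact interval 11.1 to 349.6), and neither its protein nor its action was measured.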

How the results depend on the processing

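The edgeR fits other than that with the deposited size factors, the scaling to total reads and the TMM-scaled limma fit were chosen after seeing the data. DESeq2 for the overlap was chosen then as well. The other settings were planned, among them fry and Fisher's exact test of the calls in a list. All 72 gene results run, those of the genes named by the fixed rule in the comparison where it named them, kept direction and call over 9 settings (648 comparisons), with leave-one-out as 1 of them. Apart from Klf6 and Lyz2, that rule took large changes already past the test in the same data. Kept calls were therefore likely beforehand and say little about other genes. Values of these genes in the other condition and genes picked after their values were seen were not run. For the 28 list results, 332 comparisons over up to 13 settings kept direction and call, 28 lost and 3 gained the call, and 0 reversed. Lists whose median turned under another scaling were not among these, so the lack of reversals under the scalings follows from that choice. All but 2 of the lost calls came from camera with an estimated correlation, by which 0 lists passed untreated and 0 with TNF (8 and 4 at an unadjusted p below 0.05), while fry passed 26 and 24 and Fisher's exact test 19 and 15. Cholesterol biosynthesis genes, untreated, also lost the call with a limit of 5 CPM (limma, adjusted p = 0.0826) and without Klf6-deleted replicate 2 (0.0610). NF-kB and TNF response genes, untreated, gained it with a limit of 0.1 CPM (0.0310) and without Klf6-deleted replicate 3 (0.0378), and macrophage identity genes, with TNF, gained it with a limit of 0.1 CPM (0.0319). The cause of these changes was not tested.

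A limit on the fold change lowers the counts by construction. Untreated, 2983 genes changed at least 1.5-fold (1914 higher, 1069 lower) and 1753 at least 2-fold (1408 higher, 345 lower). With TNF, 3168 changed at least 1.5-fold (1676 higher, 1492 lower) and 1767 at least 2-fold (953 higher, 814 lower). Scaling to total reads shifts every gene upward in Klf6-deleted cells, and gave 2408 lower genes untreated, 7038 higher and 1716 lower with TNF, and 4930 with a more positive effect with TNF. Under the other scalings and tests the counts stayed within 1.5 times those reported, with edgeR and TMM at 7219 untreated and DESeq2 at 6244. With the replicate number as a block (replicate block), 7284 genes changed untreated and 6473 with TNF.

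Leaving out 1 library at a time gave 6622 to 6857 genes untreated, 6047 to 6619 with TNF and 5926 to 6437 for the difference between the effects. The share of TNF-responsive genes that were lower was 76.5% to 78.4%, and 61.0% to 85.1% over the other settings. Those other settings changed how the responsive genes were chosen and not the comparison of genotypes. Scaling to total reads, which gave 1716 lower genes with TNF in place of 3608, was not run for this share. The overlap of genes higher without and lower with TNF had an odds ratio of 0.956 at an adjusted p below 0.01 (exact p = 0.420) and 0.970 with DESeq2 (exact p = 0.570), and reversed to 1.68 for changes of at least 1.5-fold (exact p = 6.2e-10). Leaving out 1 library gave 0.840 to 0.928, the highest without Klf6-deleted replicate 2 (exact p = 0.142). The overlap of genes lower without and higher with TNF was 0.855 for changes of at least 1.5-fold (exact p = 0.140), and the cause of these changes was not tested. For the response to TNF, a joint edgeR fit, which has no 2-fold limit, called 4947 genes higher and 5108 lower in Lyz2cre and 4321 and 4619 in Klf6-deleted cells. With a 2-fold limit it called 1645 and 2662 in Lyz2cre and 787 and 2189 in Klf6-deleted cells.

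In simulated untreated libraries (12715 genes), limma recovered 52% of genes with the smallest change simulated, 84% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, and with TNF (11717 genes) 52%, 88%, 94% and 100%. For the difference between effects (13062 genes) the shares were 28%, 50%, 72% and 88%. False calls made up 4.71%, 8.74% and 7.03% of calls. In each simulation 200 genes were changed, far fewer than were called in the data, so a broad shift in scale between the genotypes was not tried. Not run were the filter with deposited q values and the standard errors from deposited p-values, since the tables hold neither, and a pseudocount of 1 as an alternative, since it is the setting reported.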

Other observations

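The tests in this part were chosen after the results were seen. Of the 11425 genes tested in both tables, 147 differed at least 4-fold the same way in both, 140 higher and 7 lower in Klf6-deleted cells. Among the 7 was Pirb, an inhibitory receptor of myeloid cells, at 2832 against 14774 normalized counts without TNF and 2836 against 23516 with it. Its paralog Pira2 was at 80.9 against 388 and 92.4 against 663, and reads shared between these copies make both levels uncertain. Pirb, Pira2 and Eps8l1, another of the 7, lie on chromosome 7 between 3711409 and 4480487 (GRCm38). Gpr137b-ps, also among them, lies on chromosome 13 from 12615057 to 12650388, the chromosome of Klf6. The strain background of the mice is not stated, so whether these lower levels came from loss of Klf6 or from other differences between the mice, such as strain variants, was left open. Pirb, Pira2 and Gpr137b-ps were picked after their values were seen.

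Genes that were at least 2-fold lower with TNF than without in Lyz2cre cells, by levels set across separately normalized tables, numbered 2483 among those tested. This selection was not run with ratios recentred on their median, which lowers the number of such genes. Of these, 1550 (62.4%) were higher in TNF-treated Klf6-deleted cells, against 16.1% of the 9060 other genes (Fisher's exact test, two-sided, odds ratio 8.68). The Lyz2cre TNF libraries served both to select these genes and to compare them, so a part of this could come from the selection. The median log2 change of these genes was 0.56, and in 20 simulations with no effect of genotype and genes selected anew each time it lay between 0.00539 and 0.0171. Such simulations drew only the spread between libraries, so a deviation shared by all Lyz2cre TNF libraries was not sized.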
